A study of Mus musculus with 12 samples.

How the data were processed

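RNA sequencing was done on lung cells of female Balb/c mice that had been injected intravenously with 4T1 cells, a mouse mammary carcinoma line that colonises the lung. Per the labels' protocols, the lungs were digested with enzymes, red blood cells were lysed, and CD45-Ter119- cells were sorted by flow cytometry. CD45 marks blood leukocytes and Ter119 marks red blood cells, so the gate removes both. RNA was extracted from the sorted cells with magnetic beads and amplified before library preparation. The titles place 12 libraries in 4 groups of 3, Cherry- and Cherry+ cells at day 5 and at day 10 after the injection. The labels do not say what the Cherry label marks beyond calling the injected line a labelling one. As background, labelling lines of this kind release a cell-penetrating mCherry protein that neighbouring host cells take up. Cherry+ cells then lie near tumour cells, and Cherry- cells come from the rest of the lung.

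The authors deposited 1 table of 32958 rows, each with an identifier of the UCSC known-gene series, and 12 columns of values on a log2 scale. The submitters' processing notes name RSEM 1.2.29, Bowtie2, DESeq2 1.12.4 and the mm10 genome build, without a role or an order. How each was used, and which transform gave the log2 values, is not given in the sources used here. From the values themselves, 7764 rows held 0 in every library, and 25194 rows held a value other than 0 in every library. The lowest value was -2.21, and the medians over the genes tested lay between 8.70 and 8.82 in all libraries. These features are those of a shrunken, library-size-adjusted log2 transform. On such a scale the differences of genes with few reads are pulled towards 0, so folds of low genes may be understated here. This was not tested. Read counts were not used here, so the depth of each library is unknown, and no interval that rests on counting error was computed.

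The rows are called genes below. None of the 32958 identifiers matched the gene name tables used here (0 in either), and the deposited table does not pair its identifiers with names. No name was guessed. For this reason the 36 lists of marker and pathway genes fixed before the data were examined could not be tested, nor could markers of other cell types in the sort. Checks of GC content and gene length were void because no gene of the table had a value. The rule for named genes, also fixed before the data were examined, took per contrast the 10 largest rises and falls with a gene symbol, an adjusted p under 0.05, a level of at least 50 on the linear scale in the higher group and the same direction in all 3 same-numbered library pairs. Without symbols it was reduced to the 2 largest rises and the 2 largest falls of the day 5 comparison that met the other conditions.

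Genes were kept when at least 3 of the 12 libraries reached 10 on the linear scale. That minimum had been set for scaled counts, and it was moved to the log2 scale (3.32) once the unit was known. It left 15842 genes. The test was limma 3.58.1 in R 4.3.3, fitted to the 4 groups together with a mean-dependent prior for the variance, which gave 8 residual degrees of freedom. The contrasts tested were Cherry+ against Cherry- at day 5 and at day 10, the difference between these differences, and day 10 against day 5 within Cherry+ and within Cherry- cells. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene is called changed at an adjusted p under 0.05. Differences are in log2 units of the deposited values, Cherry+ minus Cherry- or day 10 minus day 5. No label says that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. Figures were drawn with matplotlib 3.10.9.

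Simulated data gave each gene its mean over the 12 libraries and its residual spread, the same in all groups. The procedure was tested on these data, with 200 of 15842 genes changed by a known amount and no other difference between groups. At a change of 1 log2 unit it recovered 50.8% of the changed genes in the day 5 Cherry comparison, 44.0% at day 10, 26.2% for the difference between the days, 52.3% for the change between days in Cherry+ cells and 44.1% in Cherry- cells. At 2 log2 units it recovered 81.5%, 69.8%, 60.9%, 89.9% and 77.6%. At 0.5 log2 units it recovered 10.5%, 6.94%, 0%, 10.6% and 10.8%. False calls numbered 5 of 96, 3 of 78, 5 of 75, 9 of 112 and 0 of 89 calls. The simulated noise was drawn separately for each gene and library. Real libraries also deviated together across genes, for instance at a correlation of 0.651 between day 5 Cherry- replicate 1 and day 10 Cherry- replicate 2. The false calls given here therefore do not measure the error rate in the real data. The real Cherry comparisons called 6070 genes at day 5 and 6160 at day 10, many more than the 200 simulated. With more genes changed the Benjamini-Hochberg cut-off is looser, so the recovery in those comparisons may be higher than the shares given here.

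Cherry- and Cherry+ libraries share replicate numbers, and within a day same-numbered libraries also share a letter in their source names. No label says that this pairs them. At day 5 the deviations of same-numbered libraries from their group means correlated across genes at 0.254, 0.161 and 0.228. All lay above the limit of 0.1 set for a pair, so the numbers were taken to pair the day 5 libraries. There 6 of 6 libraries correlated best with their own number. These 6 are not separate results, since deviations within a group cancel out and each pair is counted from both sides. The limit alone does not show pairing, since day 5 Cherry- replicate 1 correlated at 0.651 with day 10 Cherry- replicate 2, of another number and letter. At day 10 and between the days not every pair passed the limit. The test without pairs stayed the one reported, as fixed before the data were examined.

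Alternatives fixed in advance were rescaling by median ratios, quantile normalisation, no filter and a stricter filter at 50, a variance prior without a trend, library quality weights, a fit of only the groups compared, a replicate block and leaving out each library in turn. Cyclic loess normalisation and a fit without 3 libraries that stood apart were added after the data had been seen. Tests on read counts and other pseudocounts were not run, since the values are on a log2 scale and no counts were used.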

Results

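The data are log2 expression values of 32958 genes in 12 libraries of CD45-Ter119- lung cells from mice carrying 4T1 cells, with 3 libraries each of Cherry- and Cherry+ cells at day 5 and at day 10. The series sets out to find the expression signature of the CD45- cells of the metastatic niche at different stages of the disease. Cherry+ and Cherry- cells were compared at each day for that signature, and the days for the stages. The gate does not itself remove the injected tumour cells, and whether the sort did so by other means is not given in the sources used here. Of the 15842 genes that passed the filter, 38.3% differed between Cherry+ and Cherry- cells at day 5 and 38.9% at day 10, whereas the change from day 5 to day 10 within one kind of cell reached 4.39% of genes in Cherry+ cells and 0.366% in Cherry- cells. The order of these last 2 depended on the model of the spread, since library quality weights gave 0 genes in Cherry+ and 1552 in Cherry- cells, and fits of only the groups compared gave 0 and 321. The deposited identifiers are not paired with gene names, so groups of genes are described by their levels and their behaviour across the 4 cell groups. The depth of the libraries is unknown.

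The libraries separated first by the Cherry label. The first principal component of the genes tested held 63.7% of the variance. It placed the 6 Cherry- libraries between -75.5 and -50.6 and the 6 Cherry+ libraries between 22.2 and 100.1. The second component held 11.99% and the third 8.73%. The root mean square difference between a Cherry+ and a Cherry- library averaged 1.08 log2 units at day 5 and 1.13 at day 10, over 9 pairs each. Within a group it averaged 0.617 in day 5 Cherry-, 0.543 in day 5 Cherry+, 0.404 in day 10 Cherry- and 0.646 in day 10 Cherry+ cells. Between the days it averaged 0.570 in Cherry- cells and 0.685 in Cherry+ cells, within the range of or little above the differences within groups. The median SD of a gene was larger in Cherry+ cells (0.26 at day 5 and 0.25 at day 10, n = 3) than in Cherry- cells (0.18 and 0.16, n = 3). Among the Cherry+ libraries, day 5 replicate 3 lay nearest to the Cherry- libraries and day 10 replicate 3 farthest from them.

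**Figure D1:**
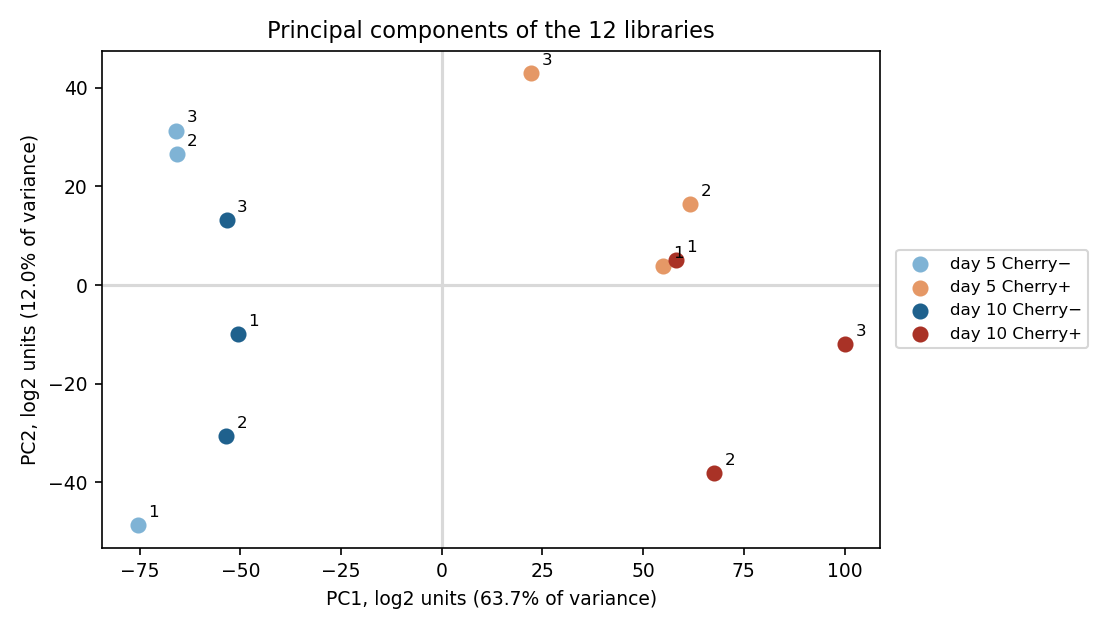
Scores of the 12 libraries on the first 2 principal components of 15842 genes, in log2 units, with 1 point per library coloured by group and marked with its replicate number. The 6 Cherry- libraries lie at or under -50.6 on the first axis and the 6 Cherry+ libraries at or above 22.2.

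At day 5, when the labelled cells can first be compared with unlabelled cells of the lung, 2996 genes were higher and 3074 were lower in Cherry+ than in Cherry- cells. The falls were the larger changes. Genes that rose did so by a median of 0.82 log2 units and genes that fell by a median of -1.24, with a median standard error of 0.22. Of the genes changed by at least 1 log2 unit, 1092 rose and 1887 fell, so that falls made up 63.3%. After cyclic loess this share was 55.1%, and as low as 52.8% with 1 day 5 library left out. The changes reached from -4.17 to 5.17. At an unadjusted p under 0.05 there were 7515 genes, where chance alone gives 792. Which direction held more calls depended on the scaling, with 3206 higher and 2895 lower after rescaling by median ratios, 3297 and 2842 after quantile normalisation, and 2999 and 2961 after cyclic loess.

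On the deposited values, the direction of the day 5 change depended on the level of the gene. Here and at day 10 the level classes were counted on these values only, not after cyclic loess, which removes trends with level between libraries. Among the 2479 genes with a mean level under 5, 80 rose and 670 fell. Among the 2157 genes with a mean level over 11, 754 rose and 310 fell. Of the 100 most abundant genes, 34 rose and 10 fell. In the low class, day 5 Cherry- replicate 1 lay above its group mean by a median of 0.45 log2 units, and the other 2 libraries lay below it. An offset at low levels was not confined to that library. Over all 25194 rows with a value, the library medians at the 2 days lay between 5.74 and 6.27 in Cherry- cells and between 5.02 and 5.58 in Cherry+ cells.

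The gene with the largest rise at day 5 was uc008nwt.2, with a level of 6.58 ± 0.40 (SD, n = 3) in Cherry- and 11.75 ± 1.34 (SD, n = 3) in Cherry+ cells. The difference of 5.17 ± 0.62 (SE) corresponds to 36.0-fold, with an adjusted p of 9.25e-05 in limma. It was 4.55 without day 5 Cherry+ replicate 1 and 5.88 without replicate 3. At day 10 its difference was 2.56 ± 0.62 (SE, adjusted p = 0.00729), between 8.66 ± 0.77 and 11.22 ± 0.80 (SD, n = 3). The next was uc007lko.1, at 5.80 ± 0.30 in Cherry- and 10.28 ± 1.41 in Cherry+ cells (SD, n = 3) at day 5, a difference of 4.48 ± 0.70 (SE, adjusted p = 0.000539), which was 3.73 without day 5 Cherry+ replicate 1 and 5.13 without replicate 3. Its day 10 difference of 1.83 ± 0.70 (SE) missed the threshold with an adjusted p of 0.0591. It passed at 2.60 without day 10 Cherry+ replicate 3 (adjusted p = 0.00820), and also without day 5 Cherry+ replicate 1 (0.0291) or 3 (0.0328), after quantile normalisation (0.0240) and with library quality weights (0.0339), within a range of 0.000752 to 0.201 over the alternatives. The day 10 difference was not shown to be smaller than that of day 5 for either gene (adjusted p of the difference between the days 0.334 and 0.378), except without the 3 libraries that stood apart, a fit chosen after seeing the data (0.0448 and 0.0447).

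The largest falls were those of uc007txv.1 and uc008jjn.2, and both were seen at both days. The level of uc007txv.1 was 11.06 ± 0.23 in Cherry- and 6.89 ± 0.26 in Cherry+ cells at day 5 (SD, n = 3), a difference of -4.17 ± 0.23 (SE, adjusted p = 1.27e-06). At day 10 it was 10.69 ± 0.06 and 6.04 ± 0.48 (SD, n = 3), a difference of -4.65 (adjusted p = 2.85e-07). The level of uc008jjn.2 was 11.69 ± 0.31 in Cherry- and 7.65 ± 0.58 in Cherry+ cells at day 5 (SD, n = 3), a difference of -4.04 ± 0.39 (SE, adjusted p = 2.32e-05). At day 10 it was 12.09 ± 0.46 and 7.14 ± 0.75 (SD, n = 3), a difference of -4.95 (adjusted p = 3.08e-06). A change in the same direction in the 3 same-numbered pairs at day 5 was a condition for choosing all 4 genes.

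At day 10, 2754 genes were higher and 3406 were lower in Cherry+ than in Cherry- cells. The median change was 0.77 log2 units among genes that rose and -1.28 among genes that fell, and the changes reached from -5.47 to 3.53. Of the genes changed by at least 1 log2 unit, 914 rose and 2251 fell, so that falls made up 71.1%. Of the 2479 genes with a mean level under 5, 90 rose and 651 fell, and of the 2157 genes over 11, 574 rose and 416 fell. Among the 100 most abundant genes 19 rose and 24 fell. The balance of all calls depended on the scaling, since falls made up 55.3% of the day 10 calls on the deposited values and 43.2% after quantile normalisation (3645 higher and 2777 lower), which moved the median difference of all genes from -0.05 to 0.11.

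**Figure D2:**
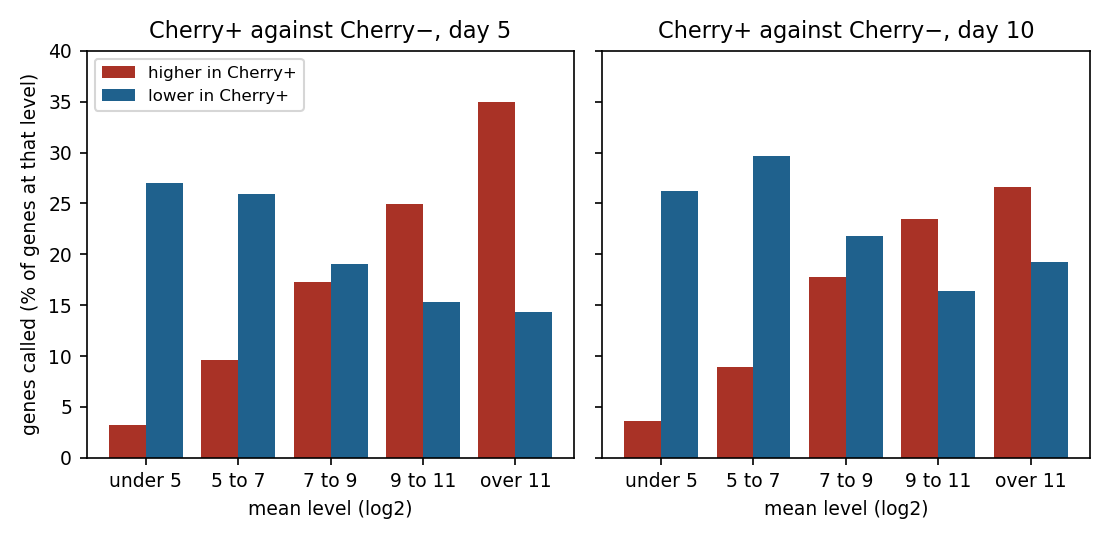
Share of genes called higher (red) or lower (blue) in Cherry+ than in Cherry- cells, in percent of the genes in each class of mean log2 level, at day 5 (left) and day 10 (right). In the lowest class 27.03% of genes fell and 3.23% rose at day 5, and in the highest class 14.4% fell and 35.0% rose.

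Most of the signature was present at both days. There were 1929 genes higher in Cherry+ cells at both days, where independent lists of these lengths would share 521, and 2398 genes lower at both days, where independent lists would share 661. The 2 comparisons have no library in common, but they share 1 estimate of the spread for each gene. Genes with a low spread are favoured in both lists, so the numbers for independent lists may be too low a mark. Across the 15842 genes the day 5 and day 10 differences correlated with a Pearson r of 0.866 and a Spearman rho of 0.816, with the caution that genes are not independent replicates. Of the genes called at day 5, 96.5% had the same sign at day 10 and 71.3% were also called there. Genes called at 1 day alone numbered 1726 for day 5 and 1816 for day 10, which does not show that they differed between the days. There were 17 genes called higher at day 5 and lower at day 10, and 0 called lower at day 5 and higher at day 10.

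**Figure D3:**
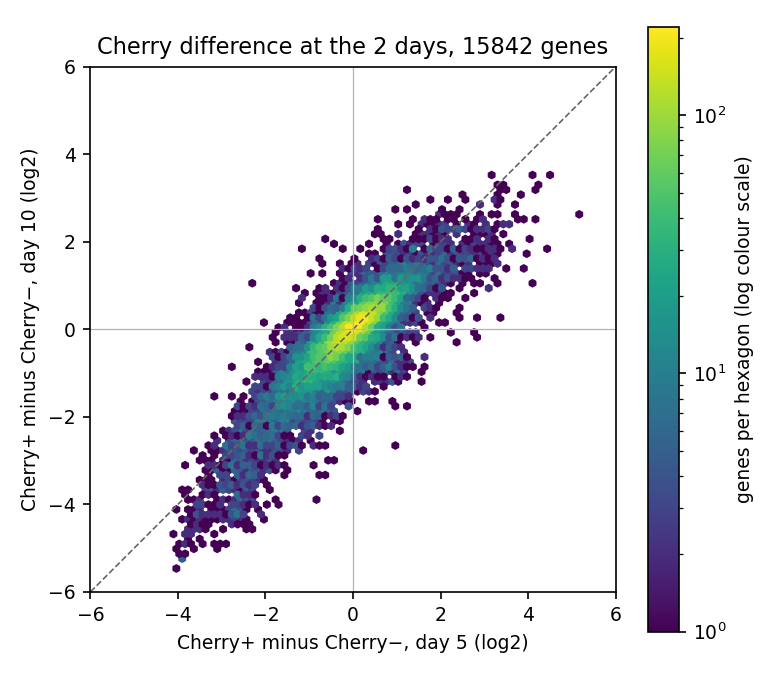
Difference between Cherry+ and Cherry- cells in log2 units at day 5 (horizontal) and at day 10 (vertical) for 15842 genes, with hexagons coloured on a log scale by the number of genes and a dashed line of equal values. The differences at the 2 days correlated with an r of 0.866 across genes.

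The difference between the day 10 and the day 5 signature was tested for each gene as an interaction in limma, and 0 of 15842 genes passed. The smallest adjusted p was 0.192. At an unadjusted p under 0.05 there were 1613 genes, where chance gives 792. The median standard error of this contrast was 0.31 log2 units, larger than that of either day. The count rose to 107 without day 5 Cherry+ replicate 3, to 161 without day 10 Cherry+ replicate 1 and to 11 without day 10 Cherry+ replicate 3, and to 18 with library quality weights.

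In Cherry+ cells, 214 genes were higher and 481 were lower at day 10 than at day 5. The falls were again the larger changes, with 386 of at least 1 log2 unit against 61 such rises. The excess in the number of falls depended on day 10 Cherry+ replicate 3. Without that library 197 genes were higher and 198 lower. Without the 3 libraries that stood apart, that one among them, 555 were higher and 744 lower. The 481 genes that fell had median levels of 10.19 in day 5 Cherry-, 9.21 in day 5 Cherry+, 10.03 in day 10 Cherry- and 7.68 in day 10 Cherry+ cells. Of these, 393 were also called lower in Cherry+ than in Cherry- cells at day 10 and 214 at day 5. The 214 genes that rose had median levels of 9.37, 9.29, 9.52 and 10.11 in the same order, and 129 of them were called higher in Cherry+ cells at day 10. At day 5, 44 of them were called higher and 44 lower. Each of these overlaps shares Cherry+ libraries with the contrast that picked the genes, so none is independent of the selection. The count of 695 genes rested on single libraries and on the spread of the other groups. It was 0 without day 10 Cherry+ replicate 2, 98 without day 5 Cherry+ replicate 3, 207 without day 5 Cherry+ replicate 1, 395 without day 10 Cherry+ replicate 3 and 1655 without day 10 Cherry+ replicate 1. Without a Cherry- library, whose only part here is in the estimate of the spread, it was 348 and 376 (day 5 replicates 2 and 3) and 320 and 336 (day 10 replicates 1 and 2). It was 0 when only the 6 Cherry+ libraries were fitted and 0 with library quality weights.

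In Cherry- cells, 58 genes were higher and 0 were lower at day 10 than at day 5 in limma, with 1211 genes at an unadjusted p under 0.05. The rises had a median of 2.00 log2 units and lay between 0.81 and 3.39, and 55 of them were of at least 1 log2 unit. That no gene fell depended on the model of the spread, since library quality weights gave 1123 genes higher and 429 lower, and a fit of the 6 Cherry- libraries alone gave 304 higher and 17 lower. The mean level of the set was 6.34 ± 0.04 in day 5 Cherry-, 7.23 ± 0.20 in day 5 Cherry+, 8.32 ± 0.40 in day 10 Cherry- and 7.61 ± 0.20 in day 10 Cherry+ libraries (SD, n = 3). Relative to Cherry- cells, 34 of the 58 genes were called higher and 4 lower in Cherry+ cells at day 5. At day 10, 7 were called higher and 26 lower. All of these counts share their Cherry- libraries with the contrast that picked the genes. Between the days in Cherry+ cells, a contrast with no library in common, the set had a median difference of 0.30 log2 units. It was above 0 in 43 genes and below 0 in 15, by sign alone. Of the 58, 18 had an unadjusted p under 0.05, against 3317 of all 15842 genes, and 5 were called higher and 0 lower. The Cherry- libraries enter the spread behind these p-values, which are therefore not independent of the selection. The number of genes called fell to 1 without day 10 Cherry- replicate 1 and to 1 without replicate 2, to 7 without day 5 Cherry- replicate 3 and to 21 without replicate 2. The size of the rise moved little in these fits, with medians of 1.88, 1.92, 2.03 and 2.03 log2 units for the 58 genes. Their selection with all the libraries favours such stability. The number of genes called rose to 124 without day 10 Cherry- replicate 3, to 245 without day 5 Cherry+ replicate 3 and to 108 without day 10 Cherry+ replicate 3.

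**Figure D4:**
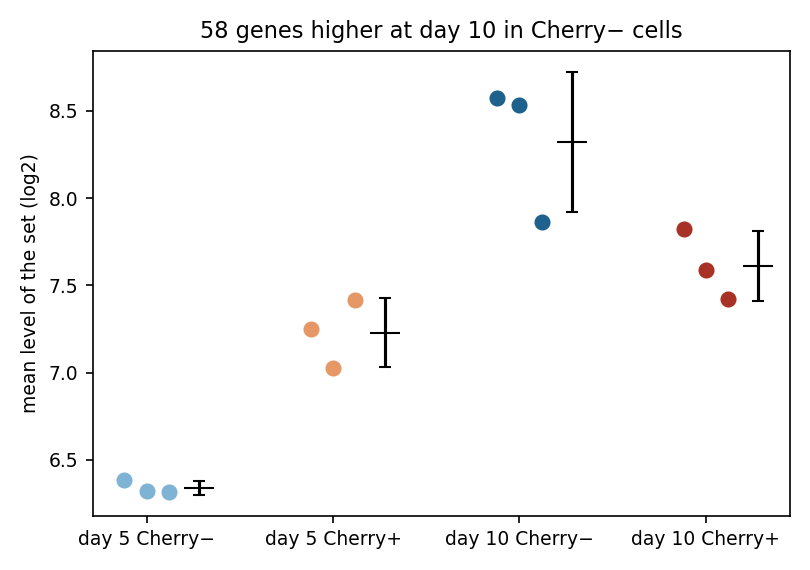
Mean log2 level of the 58 genes that were higher at day 10 in Cherry- cells, with 1 point per library in the order of replicates 1 to 3 and the group mean ± SD (n = 3) as black bars. The day 5 Cherry- libraries lie between 6.31 and 6.39 and the day 10 Cherry- libraries between 7.86 and 8.57.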

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

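The Cherry comparisons kept their counts within 1.5 times under every alternative run, at 4561 to 9056 genes at day 5 and 4683 to 7095 at day 10. The replicate block gave 6173 genes at day 5, 6199 at day 10 and 0 for the difference between the days, so pairing changed none of these counts by over 1.5 times. At day 10 the same-numbered libraries correlated at -0.142, 0.572 and 0.107, 2 of 3 above the limit, and 2 of 6 libraries correlated best with their own number. Between the days same-numbered Cherry+ libraries deviated in opposite directions (-0.391, -0.194 and -0.443), so the numbers do not pair the libraries there, and the block gave 196 genes in Cherry+ and 51 in Cherry- cells. Of the values of the 4 named genes under the alternatives, 420 kept their direction and side of the threshold, 14 newly passed it, and 2 changed direction, both below the threshold in the change of Cherry+ cells between the days. These were uc008nwt.2, from -0.53 to 0.0837 without day 5 Cherry+ replicate 1 (-1.25 to 0.0837 with 1 library left out), and uc008jjn.2, from -0.51 to 0.0160 without the 3 libraries named below.

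The difference between the days, 0 genes, ranged from 0 to 161 with 1 library left out, was 18 with library quality weights, and was 603 without the 3 libraries that stood apart. The 695 genes of Cherry+ cells became 276 without a filter, 0 with quality weights, 0 with only the groups compared and 1299 without those 3 libraries, and 0 to 1655 with 1 left out. The 58 genes of Cherry- cells became 31 without a filter, 1552 with quality weights (1123 higher, 429 lower), 321 with only the groups compared (304 and 17), 110 after quantile normalisation, 95 after cyclic loess and 431 without the 3 libraries, and 1 to 245 with 1 left out. Cyclic loess and the fit without 3 libraries (day 5 Cherry- replicate 1, day 5 and day 10 Cherry+ replicate 3) were chosen after seeing the data. Dropping libraries for their distance tends to lower the spread, which can raise counts, but single drops went both ways. The 695 genes of Cherry+ cells became 98 without day 5 Cherry+ replicate 3, 395 without day 10 Cherry+ replicate 3 and 484 without day 5 Cherry- replicate 1. The 58 genes of Cherry- cells became 245, 108 and 40 in the same order. Fitting only the groups compared leaves fewer degrees of freedom and their own spread, and the filter sets how many genes are tested. The cause of the other shifts was not tested. The quality weights stopped before their set tolerance. Pseudocounts, count models and gene list tests were not run. For the difference between the days, the fit of only the groups compared is the fit reported.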

Other observations

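The tests on the level trend behind the falls, on the 58 genes, on the shift of the Cherry- profile and on regroupings at an unadjusted p were chosen after the results were seen. Those on day 5 Cherry- replicate 1, on day 5 Cherry+ replicate 3 and on the splits of 3 against 3 had their predictions written before the tests were run. Both libraries had, however, been singled out from the data themselves.

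For the 17 genes called higher in Cherry+ cells at day 5 and lower at day 10, the adjusted p for the difference between the days lay between 0.192 and 0.198, so none passed in limma. Of these, 12 are among the 58 genes that rose in Cherry- cells, an overlap that the shared Cherry- libraries favour by construction. The 58 genes moved together, with a median correlation between pairs of genes of 0.756 over the 12 libraries, to which their joint selection contributes.

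Falls outnumbered rises among the large Cherry differences, at 63.3% of genes changed by at least 1 log2 unit at day 5 and 71.1% at day 10. Day 5 Cherry- replicate 1 had low genes above its group (a median of 0.45 log2 units over 2479 genes), but without this library the day 5 share was 62.0%, which argues against it as the whole cause. Cyclic loess, which removes trends with level between libraries, left 62.8% at day 10, and at least 60.6% without any one day 10 library, which argues against such a trend as the whole cause there. At day 5 it left 55.1%, and 52.8% without one library, so that a trend with level and a real excess of falls cannot be told apart against the limit of 55%. A loss of transcripts of cell types that do not take up the label may contribute and stays untested without gene names.

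The rise of 58 genes in Cherry- cells at day 10 might come from Cherry+ cells carried over into the Cherry- sort. A mixture cannot exceed both its parts. Each day 10 Cherry- library was therefore held out, 58 genes were picked by the smallest p for a rise without it, and their levels in it were set against day 10 Cherry+. The median lay above Cherry+ by 1.18, 0.90 and 0.36 log2 units in replicates 1, 2 and 3. Of the 58 genes, 48, 47 and 40 lay above, while no Cherry+ library deviated from its group by a median over 0.21. This argues against carry-over of cells with the mean Cherry+ profile as the cause for the set as a whole. Carry-over of only some kinds of Cherry+ cells was not tested. For the 58 called genes, replicate 3 had a mean level of 7.86, near the 7.82 of day 10 Cherry+ replicate 1. In each held-out library the genes picked without it lay above day 5 Cherry- by a median of at least 1.35, which argues against a single library. The median rise of the 58 called genes was 1.88 without replicate 1 and 1.92 without replicate 2, where the number of calls fell to 1 in both cases. Those 2 medians add no support, since the called genes had been picked with all 3 replicates. A response of the unlabelled lung to the growing tumour, and a change in the mix of its cell types, both stay open and untested.

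Day 5 Cherry+ replicate 3 lay at 0.568 on an axis that runs from 0 at the day 10 Cherry- mean to 1 at the day 10 Cherry+ mean, where the other 2 day 5 Cherry+ libraries lay at 0.793 and 0.851. After cyclic loess it lay at 0.537 against 0.791 for the nearest of the others, so a trend with level does not account for it. Cherry- cells in this library might do so. Of the 2251 genes lower in Cherry+ cells at day 10 by at least 1 log2 unit, the 1728 that lay as far below Cherry- in the other 2 day 5 Cherry+ libraries put the share of such cells at a median of 9.16% (quartiles -0.389% and 22.2%), taking the mean of the day 5 Cherry- libraries as their profile. That share allows a displacement of -0.09 log2 units for the 914 genes higher in Cherry+ cells at day 10 by at least 1 log2 unit, and they lay at -0.96, while the other 2 libraries differed by 0.02, which argues against carry-over alone. A weaker response in this library or another mix of labelled cells stays open.

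A hypothesis tested here is that the Cherry- profile itself moved towards that of Cherry+ cells between the days. With 1 Cherry- library held out as the origin and the axis drawn from the others, the day 10 Cherry- libraries lay above those of day 5 in 9 of 9 differences along the day 5 axis, by a median of 0.0906 of its length (0.0407 to 0.140). Along the day 10 axis it was 9 of 9, by a median of 0.0923. The 9 differences share 6 libraries and are not independent. These values go with such a shift, and a larger share of Cherry+ cells in the day 10 Cherry- sort could give the same. The day 10 Cherry+ libraries also lay past the day 5 Cherry+ mean, at 1.03, 1.03 and 1.24 of the day 5 axis length. The root mean square difference between Cherry+ and Cherry- libraries averaged 1.08 log2 units at day 5 and 1.13 at day 10. A shift of both kinds of cells between the days therefore cannot be told apart from a move of Cherry- towards Cherry+ cells.

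Other splits of the libraries were fitted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the day 5 Cherry comparison 1 of 10 splits, the real one, reached 6070 genes, and the highest other gave 0, including the other splits that part all 3 pairs. At day 10 it was 1 of 10 with 6160 genes, and the highest other gave 0. In these 2 comparisons every other split puts Cherry+ and Cherry- libraries into one group, so the Cherry difference itself enters the spread. Their counts of 0 therefore give no measure of what chance would call. For the change between days in Cherry- cells, 1 of 10 splits, the real one, reached 58 genes, and the highest other gave 0. In Cherry+ cells it was 1 of 10 with 695 genes, and the highest other gave 473, in the split that exchanges day 5 replicate 3 with day 10 replicate 3. For the difference between the days a count of 0 decides nothing, since no regrouping can give fewer. The days were therefore regrouped within Cherry- and within Cherry+ cells at an unadjusted p under 0.05, with the additive effects of Cherry and day taken out first, so that the day change itself could not enter as an interaction. Cherry- and Cherry+ libraries were exchanged separately, which can part same-numbered pairs. Of 100 regroupings, the real one included, 22 gave 1613 genes or more, the count of the real one, so chance is not excluded. The highest other gave 4539 at that p, and the highest count of calls in another regrouping was 1232, which points to a structure of the libraries within the groups. The deviations from the group means correlated across genes at 0.651 between day 5 Cherry- replicate 1 and day 10 Cherry- replicate 2, at 0.606 between the former and day 10 Cherry+ replicate 2, and at 0.572 between the 2 same-numbered day 10 libraries, which also share a letter in their source names.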
